A study of Nostoc sp. MG11 with 2 samples.

How the data were processed

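RNA was measured by sequencing in 2 libraries of Nostoc sp. MG11, a filamentous cyanobacterium, grown in BG11 medium under continuous light at 25 °C. One library came from cells harvested without drying (0 h) and the other from cells spread on plates and dried for 3 h in the same light. Total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols; removal of ribosomal RNA and strandedness are not given in the sources used here. Trimmomatic 0.36, Bowtie2 2.3.4 and HTSeq 0.9.1 are listed, per the submitters' processing notes. The genome build, the annotation and the options used with these tools are not given in the sources used here. The deposited values are whole-number read counts per locus tag, not normalized, with different totals in the 2 libraries. Per the file headers, each count column is named replicate 3 of its condition; other replicates were not analysed here. Both tables list 7680 locus tags in the same order, and 0 rows lack a tag.

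The tables pair the tags with no gene name, product or coordinate, and no genome or annotation was used here. A total of 37 gene lists (photosystems, phycobilisome, antioxidant enzymes, chaperones, trehalose and sucrose metabolism, DNA repair and others) had been fixed before the data were examined, and 0 of them could be used. The rule for naming was also fixed then. Because the tags carry no names, it came down to the 2 tags in each direction whose counting interval lay farthest from no change, with a count of 0 ranked as 3 counts. Tags that the rule would have named for a product, a list or a high count are given without identifiers.

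Tags with a sum of at least 10 counts over both libraries entered the comparison, which left 7226 and set aside 454. Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. The effective size of the desiccated library was 0.781 times that of the control, although its total was 1.243 times as large. The ratio of desiccated to control was formed per tag, and its 95% interval is the exact Clopper-Pearson interval of the desiccated share of the pair's reads (scipy 1.17.1). A tag was called higher or lower when the scaled ratio was at least 2-fold and the interval excluded a ratio of 1. A count of 0 was set to a floor of 3 counts per library for the fold. This allows for the counting error of the 0 but not for that of the other library's count. Medians over groups of tags used log2 of the scaled count plus a pseudocount of 0.5. Folds and intervals of single tags used no pseudocount.

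With 1 library per condition no test of the conditions can be made, and no p-value is given. The intervals, floors and binomial intervals of shares cover counting error only, because reads without molecular identifiers are not independent molecules and no replicate spread is measured. The libraries held 1792841 and 2229181 counts, so that 3 counts correspond to 1.673 and 1.346 CPM. The rule was tested on simulated data with Poisson counts at the depths of this comparison, over 7200 tags. It called 100% of 50 tags made 4-fold higher, 97.9% of 48 made 4-fold lower, 100% of 50 made 8-fold higher and 97.9% of 48 made 8-fold lower. It also called 0.685% of 7004 unchanged tags. Both simulated libraries had the same profile apart from the tags made higher or lower. TMM there gave a size ratio of 1.2406 against a true 1.2434, so the gap between scalings seen in the real libraries was absent. The simulation therefore covers counting error, and neither the choice of scaling nor replicate spread.

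Alternatives covered the scaling (total counts, DESeq2 1.42.0 size factors, upper quartile, and totals without the 10 most counted tags of either library), the filter, the fold and the interval. Thinning the desiccated library to the control total, and the alternatives for the medians by abundance, were added after seeing the data. Tests that needed rRNA or tRNA genes to be identified were not run.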

Results

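The transcriptome of Nostoc sp. MG11 was profiled before drying and after 3 h of desiccation in the light, to ask which genes respond to water loss. Each condition is represented by 1 library, so every value below describes these 2 libraries and no difference has a replicate check. The control was taken at 0 h and no undried 3 h sample was analysed. Effects of drying therefore cannot be told apart from those of elapsed time or of handling on plates, and "after desiccation" names the library. The control library held 1792841 counts and the desiccated library 2229181 counts over 7680 locus tags. Reads were found for 7497 tags in the control and 7512 after desiccation, and 111 tags had no reads in either library. Although its total was larger, the desiccated library had the lower median, 70 counts per tag against 89 in the control.

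After 3 h of desiccation 936 of 7226 tags (13.0%) were at least 2-fold higher than in the control and 512 (7.1%) were at least 2-fold lower, by TMM-scaled counts. The other 5778 tags met neither criterion. With this scaling, at least 4-fold differences were seen for 325 tags that were higher and 72 that were lower, at least 8-fold differences for 120 and 9 tags, and at least 16-fold differences for 42 and 2 tags. With total-count scaling the 4-fold counts turned round, to 169 higher and 302 lower tags, and the 8-fold counts were 63 and 42. The quartiles of the log2 ratio were -0.46 and 0.53. Its median of -0.02 is set near 0 by TMM, and was -0.68 with total counts and -0.19 with upper-quartile factors. Across tags, which are not independent replicates, the counts of the 2 libraries had a Spearman rho of 0.897.

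The split between higher and lower tags depended on how the libraries were scaled. Scaling by total counts lowered every log2 ratio by 0.67, and then 433 tags were higher and 2183 lower. The tags called higher thus made up 64.6% of all called tags with TMM and 16.6% with total counts and 66.3% with DESeq2 size factors, while upper-quartile factors gave 774 higher and 775 lower tags. Under all 5 scalings tried, 433 tags were at least 2-fold higher and 488 at least 2-fold lower. Because each scaling shifts every ratio by the same factor, these are the counts under the strictest scaling for each direction. That was total counts for higher tags and DESeq2 size factors for lower tags.

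**Figure D1:**
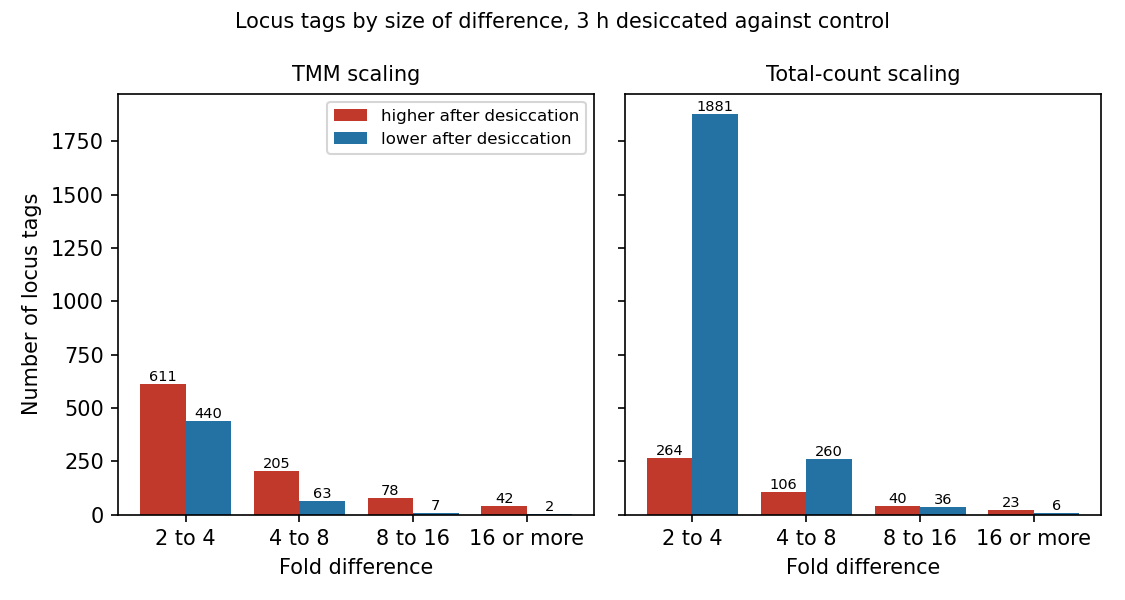
Number of locus tags (vertical axis) in each class of fold difference (horizontal axis) between the 3 h desiccated and the control library, for tags higher (red) or lower (blue) after desiccation, with TMM scaling on the left and total-count scaling on the right. With TMM, 611 tags were 2 to 4-fold higher and 440 were 2 to 4-fold lower; with total counts these numbers were 264 and 1881, whereas the class of 16-fold or more held more higher than lower tags in both panels (42 against 2, and 23 against 6).

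The tags that were higher accounted for a large part of the desiccated library. The 433 tags higher under all scalings took 7.67% of control reads and 31.2% of desiccated reads, and their median count went from 116 to 591. The 488 tags lower under all scalings took 7.63% of control reads and 1.86% of desiccated reads, with median counts of 70 and 21. These tags were selected for their ratio, so the shares describe how many reads they carry and are not separate evidence of a difference.

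The set of most counted tags differed in part between the libraries. The 100 most counted tags took 30.5% of control reads (exact binomial 95% interval 30.4 to 30.5%) and the 100 most counted tags after desiccation took 39.4% (39.3 to 39.4%). Of these, 55 tags were in both sets. The 100 leading tags of the desiccated library had taken 25.1% of control reads, and the 100 leading tags of the control took 30.9% of desiccated reads. Each set was selected on 1 of the libraries it is compared in. Among the 10 most counted tags, 7 were shared, and 1 tag led both libraries with 1.60% of control and 2.57% of desiccated reads. The other 3 of the desiccated library's leading 10 included 1 tag from rank 527 in the control and 1 from rank 268. The latter went from 937 to 23448 counts, 32.0-fold higher after TMM scaling. In the opposite direction, the tag ranked 8 in the control, with 15322 counts, ranked 50 after desiccation with 5540 counts.

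Single tags were ranked by the end of the counting interval nearest to no change. The upward difference that ranked first was that of HCR01_RS23805, which had 15 counts in the control and 1081 after desiccation. It was 92.3-fold higher, with a 95% counting interval of 55.7 to 165.4, and moved from rank 6596 to rank 321. HCR01_RS14775 went from 566 to 23989 counts and was 54.3-fold higher (interval 49.9 to 59.1). It moved from rank 527 to rank 6 and made up 10761 CPM in the desiccated library, against 315.7 CPM in the control. The downward difference that ranked first was that of HCR01_RS09030, with 585 counts in the control and 36 after desiccation. It was 12.7-fold lower (interval 9.06 to 18.3), less than the fold of the 2 tags at least 16-fold lower, whose intervals reached closer to no change. HCR01_RS09495 went from 1161 to 120 counts and was 7.56-fold lower (interval 6.26 to 9.20). All 4 kept their direction with total counts, DESeq2 size factors and upper-quartile factors. This is no separate check, since these scalings shifted every log2 ratio by at most 0.67, too little to turn ratios of this size. With total counts their log2 ratios were 5.86, 5.09, -4.34 and -3.59 in that order.

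**Figure D2:**
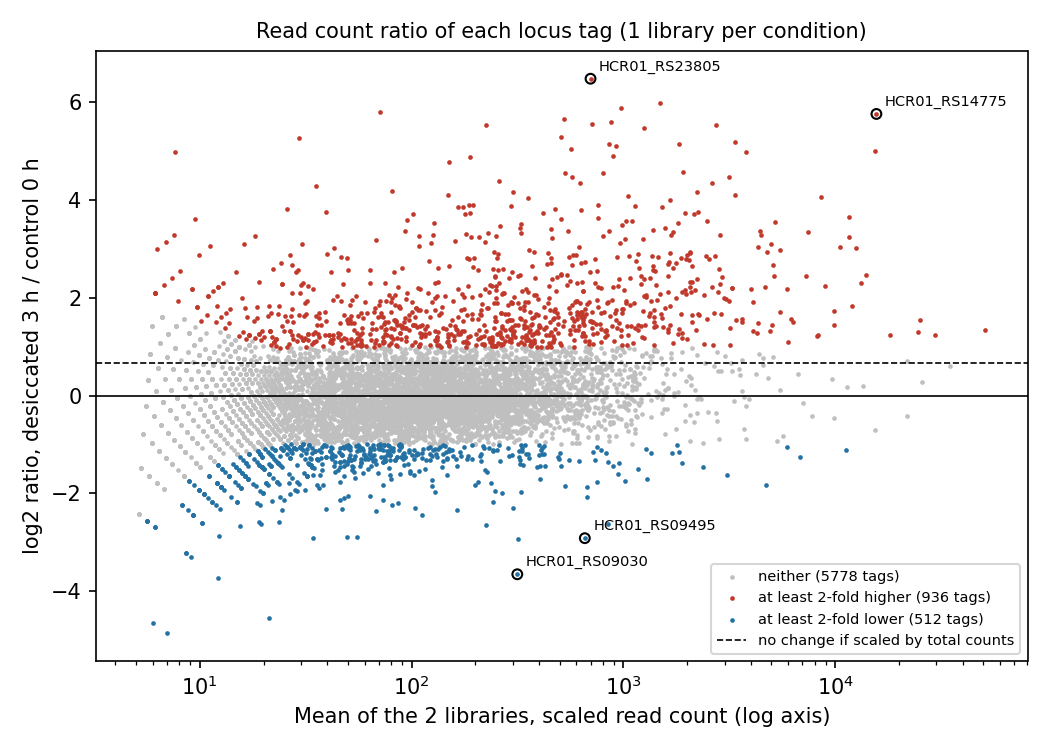
Each point is 1 of 7226 locus tags, placed by the mean scaled read count of the 2 libraries (horizontal, log axis) and by the log2 ratio of desiccated to control (vertical, pseudocount 0.5). Red points are the 936 tags at least 2-fold higher and blue points the 512 at least 2-fold lower; the dashed line at 0.67 marks where no change would lie with total-count scaling, and the 4 circled tags are those named in the text.

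Few tags with at least 10 counts in 1 library had none in the other. A single tag had 0 counts in the control and 12 after desiccation. Against a floor of 3 counts per library it was 5.12-fold higher with TMM and 3.22-fold higher with total counts. In the other direction 2 tags had 0 counts after desiccation and 12 and 14 counts in the control. Against the same floor they were 3.12-fold and 3.65-fold lower with TMM and 4.97-fold and 5.80-fold lower with total counts. The floor leaves out the counting error of the 12 or 14 counts, so the differences may be smaller. At this depth a count of 0 allows a level of up to 1.67 CPM in the control and 1.35 CPM after desiccation, as shares of the total counts.

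The ratios differed by abundance class. Tags were sorted by the mean scaled count of both libraries into 10 classes of equal size. In the most abundant class, 304 of 723 tags (42.0%) were at least 2-fold higher and 30 (4.1%) were lower, and the median log2 ratio was 0.71 (quartiles -0.03 and 1.71). In the least abundant class, 45 (6.2%) were higher and 81 (11.2%) were lower, with a median of -0.15 (quartiles -0.93 and 0.54). The mean includes the desiccated count. When tags were sorted by a random portion of the control reads alone, and the ratio was taken against the rest of the control reads, the medians of the most and least abundant classes were 0.15 and 0.24, and those of classes 2 to 9 lay between -0.09 and 0.03. Tags with few control reads passed the filter only with enough desiccated reads, which can raise the least abundant class. With total-count scaling the medians of the most and least abundant classes by mean count were -0.08 and -0.73, beside -0.68 for all tags.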

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

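With TMM scaling 936 tags were higher and 512 lower. Scaling by total counts gave 433 and 2183, totals without the 10 most counted tags of either library gave 460 and 2031, and upper-quartile factors gave 774 and 775. DESeq2 size factors (961 and 488), no filter (955 and 509), a sum of at least 50 counts (820 and 380), no interval (1003 and 615) and the thinned desiccated library (927 and 509) stayed within 1.5 times. A 4-fold limit gave 325 and 72, and an interval wholly beyond 2-fold gave 600 and 95. All 433 tags higher by total counts were among the 936, and all 512 lower tags were among the 2183. This nesting was fixed in advance, because a change of scaling shifts every ratio by the same factor. With at least 20 counts asked of the other library, 0 tags were at 0 in the control alone and 0 after desiccation alone. The median log2 ratio of the most abundant of 10 classes by mean count (0.71) was -0.079 with total counts, 0.50 with upper-quartile factors and 0.15 when sorted by a portion of the control reads. That of the least abundant class (-0.15) was -0.73, -0.28 and 0.24. Total counts lowered the ratio of each single tag by 0.67 relative to TMM, while the class medians moved by other amounts. The classes were formed anew under each scaling and the medians include a pseudocount. How much each of these contributed was not tested. Neither scaling is calibrated by a spike-in in the sources used here, and absolute amounts of RNA per cell cannot be read from either.

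No paired analysis was possible because each condition has 1 library. For the same reason leaving out a replicate was not possible. List medians, and shares without rRNA and tRNA genes, were not run because the tags carry no names. The thinned library shared 899 of the 936 higher tags and 444 of the 512 lower tags, and kept 74.6% of the called tags in the least abundant class against 99.1% in the most abundant.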

Other observations

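The 3 patterns were noticed in the data, and the tests at a lag of 50 and of 3 tags, that of the most abundant class against all tags, and that of expression level for the last tags, were chosen after their results were seen; the counts of runs were also chosen after seeing the data. Neighbours are tags that follow each other in the tables, where 7448 of 7679 steps in number are 5. The 3 patterns describe these 2 libraries, without replicates.

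Tags that differed after desiccation came in groups along the tag order. Of the 936 tags that were at least 2-fold higher with TMM scaling, 363 (38.8%) lay in 94 runs of 3 or more consecutive tags, and the longest run had 12 tags. In 1000 shuffles of the order, at most 76 tags lay in such runs and the longest run had 7 tags. The shuffles were not matched on abundance, although 42.0% of the most abundant class were higher. Adjacent abundant tags could therefore add to the runs. Of the 512 lower tags, 38 (7.4%) lay in 12 runs, against at most 24 in the shuffles, but their longest run of 4 tags was within the 5 that shuffles reached. The tag directly after HCR01_RS14775 was 36.6-fold higher (counting interval 31.5 to 42.7), while the one directly before it had a ratio of 1.49 (0.641 to 3.54), and the 2 tags before that were 11.8-fold (7.41 to 19.7) and 13.4-fold (10.3 to 17.9) higher. The tag directly after HCR01_RS09030 was 5.24-fold lower (3.13 to 9.31), while the one directly before it had a log2 ratio of 0.12. Of the tags around HCR01_RS09495, the one directly before was 2.07-fold lower (1.84 to 2.33) and the second before was 1.99-fold lower (1.58 to 2.52). The third before it was 2.75-fold higher (2.37 to 3.20), and the one directly after had a log2 ratio of -0.12. By contrast, the tags on either side of HCR01_RS23805 had log2 ratios of -0.15 and -0.47.

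The log2 ratios of directly neighbouring tags had a Pearson r of 0.389 across 6866 pairs, which are not independent replicates, and the highest value in 1000 shuffles was 0.045. A dependence of the ratio on expression level does not account for it: relative to the median of their abundance class, neighbours still had an r of 0.332 (95% block bootstrap interval 0.297 to 0.367). As the cause of this correlation, broad regional shifts are argued against by the r of 0.022 (interval -0.003 to 0.05) at a lag of 50 tags. That value cannot exclude a small shift over a long stretch of tags, which would add little to r. For reads counted into both of 2 adjacent tags, neighbours with mean counts within 2-fold were examined, and had an r of 0.429 (0.381 to 0.478). Under 0.1 had been predicted if shared reads were the cause. The value was not above that of all neighbours by more than its spread, a stricter bound than the explanation needs. This result cannot decide, because tags that share many reads would also have similar counts. Shared reads as the whole cause are argued against by an r of 0.148 (0.114 to 0.178) at a lag of 3 tags. Co-transcription of adjacent genes in operons that differ between the 2 conditions may explain the pattern, but without strands and coordinates this hypothesis stays untested.

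Abundant tags had higher ratios when sorted by the mean of both libraries. The pattern was not confined to the most counted tags. Without the 145 tags among the 100 most counted of either library, the most abundant of 10 classes still lay 0.61 above the median of all tags (interval 0.513 to 0.712). Whether reads taken by a few very high tags matter cannot be decided from this value. A class median depends little on a few tags, and the sorting still used the desiccated count. Sorting by a mean that includes the desiccated count may account for much of the pattern. In the test fixed before its result was seen, tags were sorted by a portion of the control reads and the ratio was taken against the rest. The most abundant class minus the least abundant was then -0.09 (interval -0.227 to 0.058), as predicted if the sorting were the cause. This difference cannot decide the question. The filter on the sum of both libraries let in tags with few control reads only when their desiccated count was high enough. Such a filter can raise the ratio of the least abundant class. The least abundant class rested on a median of 6 reads and stood at 0.24, apart from classes 2 to 9 (-0.09 to 0.03). In a test chosen after its result was seen, the most abundant class lay 0.159 above the median of all tags (interval 0.083 to 0.24), against 0.73 when sorted by the mean, which argues against the sorting as the whole cause for that class. How much of the pattern the sorting makes stays open.

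Of the last 1536 tags in table order, 1330 passed the filter on counts. These had a median log2 ratio of -0.20, against 0.03 for the filtered tags before them. The median control count, over all tags, was 43 against 102. Lower expression alone is argued against: relative to their abundance class the median was -0.146 (interval -0.196 to -0.075), below the lowest median of the first 8 of 10 equal stretches of tags (-0.032). The highest of these 8 medians was 0.169, in stretch 3, so a departure of this size also occurred in the other direction. Local clusters falling there by chance were examined with the unadjusted log2 ratios of the 10 stretches. Of 1000 shuffles of blocks of 20 tags, 0 gave a stretch as low as the -0.237 of the last one, the lowest being -0.211. For the unadjusted ratios this argues against such clusters as the whole cause. It cannot decide for ratios relative to abundance class, where the last stretch stood at -0.156, because the shuffled values are of unadjusted ratios. Clusters together with low expression thus stay open. Whether these tags lie on separate replicons or contigs, which could respond differently to drying, was not tested because the tables give no positions.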
